A study of Drosophila melanogaster with 10 samples.

How the data were processed

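Expression was measured in 10 samples of Drosophila melanogaster, 2 each of control larvae, Jarid2 mutant larvae, larvae labelled E(z) RNAi, control eye-antenna disc cells and Jarid2 mutant disc cells. Per the labels, flies were raised at 25 °C, biotin-labelled RNA was made from 200.0 ng of total RNA, each larval sample held 20 larvae, and each disc sample came from about 500.0 discs whose dissociated cells were separated by GFP fluorescence into 100000 cells per ml. The Jarid2 allele is, per the labels, a Minos insertion kept over a balancer chromosome, and whether the animals carried it on both chromosomes is not given in the sources used here. The deposited values are log2 expression values per probe set, as their range shows, and the submitters' processing notes name limma 3.4.3. The background correction, the normalization between arrays and the probe set summary that the authors used are not given in the sources used here. Upper quartiles were alike in all 10 arrays while medians differed between larvae and discs, so no shift between the tissues was read as a change. All 10 value columns were matched to samples by name, leaving 0 unmatched.

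The table held 18952 probe sets. The 183 control probe sets of the array maker were left out of all tests, which left 18769. The platform annotation gave 1 gene for 13647 probe sets, several for 402 and none for 4720, and genes were named only from probe sets with 1. Of the 13647, 13544 were matched to the reference gene table and 0 symbols needed updating. A gene was represented by the probe set with the highest mean over the 10 arrays, which gave 11982 genes. Gene positions served only to order the genes along the chromosome arm of Jarid2, for the test of its nearest measured genes.

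Group means were fitted to the log2 values of all 5 groups at once with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without covariates, which left 5 residual degrees of freedom and 2.78 prior degrees of freedom. All 5 groups shared one estimate of the spread, since 2 arrays per group leave few degrees of freedom. Contrasts were Jarid2 mutant against control in larvae and in discs, labelled E(z) RNAi against control in larvae, the difference between the 2 Jarid2 contrasts, and Jarid2 mutant against labelled E(z) RNAi in larvae. P-values were adjusted by Benjamini-Hochberg over the 18769 probe sets and called at an adjusted p under 0.05. All tests were two-sided. Figures were drawn with matplotlib 3.10.9.

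The sample groups, the fits, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. For each main comparison the rule named the 10 genes with the largest rise and the 10 with the largest fall among called genes whose 2 arrays of one group all lay above the 2 of the other, plus 2 each way among genes with only a CG or CR number. For the interaction and the direct contrast it named 5 each way. Jarid2, E(z) and up to 4 members of each gene list with the smallest p were added. The 27 gene lists were tested with camera at a preset correlation of 0.01 over the 135 pairs of list and contrast, adjusted together. Of these, 26 were called with the preset correlation and 0 with a correlation estimated from the data, and 7 of the pairs were called by fry, whose p-value asks whether the genes of a list move, on balance, one way without comparing them with other genes. Counts of called members were also adjusted over the list alone. Median, mean and test had the same sign in all 26 called pairs, and differed in sign in 6 of 27 lists for larval Jarid2, 4 for labelled E(z) RNAi, 11 for discs, 9 for the interaction and 4 for the direct contrast.

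The fit was tested on simulated data in which 200.0 of 18769 probe sets were changed, over 10 simulations for each comparison. The fit of all groups recovered 82.2% of 2-fold changes for larval Jarid2, 81.0% for labelled E(z) RNAi and 81.7% for discs, but with the larval spread above the disc spread 25.5%, 26.5% and 4.53% of its calls were false. The fit of one tissue alone had false shares of 6.53%, 7.11% and 7.78% and recovered 53.5%, 52.9% and 95.1%. Larval counts of all probe sets, and of the lists with several called members, are therefore given beside those of the larval arrays alone. For the overlap of the 2 larval comparisons, 100 series with unchanged groups and shared controls were simulated with the pooled larval spread. After the data were seen, 100 more were simulated with the spread of each group, and the fold changes and calls were also taken with 1 control array for each comparison, both ways round.

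Alternatives were quantile normalization of all arrays or within each tissue, median centring, omission of the dimmest 30% of probe sets, fits of one tissue or of the compared groups alone, an intensity trend or robust setting of limma's prior, array weights, the replicate number as a block, a minimum of 2-fold, the mean of all probe sets of a gene, camera with an estimated correlation, fry, and omission of each array in turn. A crossed replicate block was added after the data were seen. The number of arrays limits the precision.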

Results

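Gene expression was measured on 1-colour Affymetrix arrays in 10 RNA samples of Drosophila melanogaster, which formed 5 groups of 2 arrays. The larval groups were whole animals of the third instar: controls, larvae of a line with a Minos transposon insertion in Jarid2, and larvae labelled as E(z) RNAi. The disc groups were cells of eye-antenna imaginal discs, the larval epithelia that form the adult eye and antenna, from controls and from the same Jarid2 line. Each larval sample was made from 20 animals, and each disc sample from about 500 discs that were dissociated and separated by GFP fluorescence. Which fluorescent fraction was kept is not given in the sources used here. Jarid2 encodes a protein that associates with Polycomb repressive complex 2, and E(z) encodes the histone methyltransferase of that complex. The series title frames the comparisons as a question of which Jarid2 functions depend on that complex and which do not.

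The deposited values were on the log2 scale. Upper quartiles lay between 9.41 and 9.49 in all 10 arrays, whereas medians lay between 7.39 and 7.54 in larvae and between 5.55 and 5.62 in discs. Replicates correlated at r = 0.983 for larval controls, 0.987 for the arrays labelled E(z) RNAi and 0.995 for larval Jarid2 mutants, and at 0.997 in both disc groups, across probe sets, which are not independent replicates. The median residual SD was 0.160 in larvae and 0.0978 in discs. The number of arrays limits the precision of every comparison. The labels do not say that the replicates came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical. Changes are given as log2 differences ± standard error with n = 2 arrays per group, and adjusted p-values come from limma. A dimmer group below the lower quartile of its arrays lies near background, which makes the size of a change a lower bound. By a comparison made after the data were seen, this held for 9 of the 24 genes named by size in larval Jarid2 mutants, 5 of 24 in the arrays labelled E(z) RNAi, 2 of 24 in discs and 5 of 10 in the direct contrast.

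The Jarid2 transcript followed its labels in every array. In larvae it read 9.63 and 9.48 in controls and 4.19 and 4.26 in Jarid2 mutants, a fall of -5.33 ± 0.24 (adjusted p = 5.35e-05). In discs it read 10.14 and 10.10 in controls and 7.64 and 6.80 in mutants, a fall of -2.90 ± 0.24 (adjusted p = 0.000465), so that the mutant disc arrays kept a mean level of 7.22 against 4.22 in mutant larvae. The reduction was smaller in discs than in larvae by 2.43 ± 0.34 (adjusted p = 0.00857). In the arrays labelled E(z) RNAi Jarid2 read 9.34 and 9.53, a difference from controls of -0.12 ± 0.24 that did not pass the test (adjusted p = 0.788).

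The E(z) probe set read against its label. It read 8.53 and 8.31 in larval controls, 8.48 and 8.41 in larval Jarid2 mutants, and 9.25 and 9.56 in the arrays labelled E(z) RNAi, which were higher than controls by 0.99 ± 0.15, or 1.98-fold (adjusted p = 0.0139). The titles of those arrays name E(z) RNAi, while their genotype field reads wild type. The rise did not pass the test without the second larval control array (0.87, adjusted p = 0.0684) or without the second array labelled E(z) RNAi (0.83, adjusted p = 0.0670), nor in a fit of the larval arrays alone (adjusted p = 0.0780). In discs E(z) read 9.10 and 9.29 in controls and 9.34 and 9.50 in Jarid2 mutants, a difference that did not pass the test (0.22 ± 0.15, adjusted p = 0.605). Whether either probe set lies in a part of the transcript removed by the insertion or targeted by the RNAi is not given in the sources used here, and a probe set outside that part would not check the label.

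**Figure D1:**
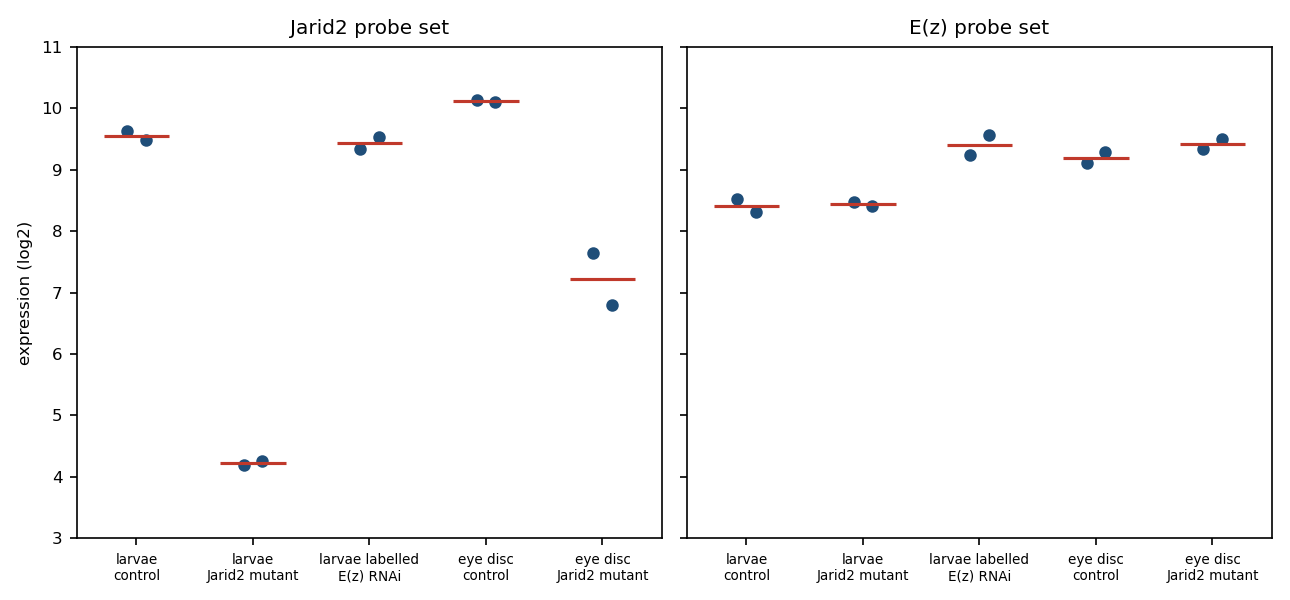
Expression of Jarid2 (left) and E(z) (right) on the log2 scale in each of the 10 arrays; points are arrays and red lines are means of 2. Jarid2 lies at 4.19 and 4.26 in the mutant larvae against 9.63 and 9.48 in their controls, while E(z) lies at 9.25 and 9.56 in the arrays labelled E(z) RNAi against 8.53 and 8.31.

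Jarid2 mutant larvae were compared with control larvae to ask which transcripts depend on Jarid2 in the whole animal. The fatty acid elongase gene Elovl7 fell by 7.45 ± 0.18 on the log2 scale, from a mean of 11.58 to 4.13 (adjusted p = 1.85e-06), a level below the lower quartiles of the mutant arrays (5.09 and 5.13), so the size of this fall is a lower bound. Antdh, a short-chain dehydrogenase gene, changed by -5.37 ± 0.30, the Jonah-family serine protease gene Jon99Ci by -4.03 ± 0.36 and the cytochrome P450 gene Cyp6a18 by -3.50 ± 0.24. The methuselah-like receptor gene mthl8 rose by 4.89 ± 0.12, from 4.89 to 9.77 (adjusted p = 1.99e-06), and its second probe set gave 4.59. The lysozyme gene LysX rose by 3.67 ± 0.48, obst-I by 3.63 ± 0.19, the peroxiredoxin gene Prx6c by 3.60 ± 0.29 and Cyp4p2 by 3.10 ± 0.20.

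Other genes that rose were AANATL4 by 3.33, the acyl-CoA binding protein genes Acbp3 by 3.07 and Acbp5 by 2.53, the amylase-related gene Amyrel by 3.03, the cuticle protein gene Cpr67Fa1 by 2.84, and the unnamed genes CG42716 by 4.07 and CG13461 by 3.62. Genes that fell included Tmlh (-3.49), lky (-3.09), the gustatory receptor gene Gr97a (-3.09), GILT3 (8.03-fold), CG32198 (-5.42) and CG11893 (-5.08). The carbonic anhydrase gene CARPB fell by 3.27 with its brighter probe set and differed by 0.03 with the other, so its direction was not settled by the array.

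Digestive and detoxification enzymes moved in both directions in these larvae. Of 40 measured midgut enzyme genes 6 rose and 3 fell, against 7 and 8 when adjusted over the list alone and 2 and 1 in a fit of the larval arrays alone, with Jon74E at 1.78 ± 0.18 and Jon25Bi at 1.87 ± 0.23 beside Amyrel and Jon99Ci. Of 64 detoxification genes 6 rose and 6 fell, against 13 and 12 adjusted over the list alone and 4 and 4 in the larval fit, among them Cyp6a14 at 2.19 ± 0.17 and the glutathione transferase gene GstE1 at 2.49 ± 0.21. Neither list ranked as a set above or below the other genes, with adjusted p = 0.32 for midgut enzymes and 0.671 for detoxification.

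The measured Polycomb targets barely moved in the mutant larvae. Of 78 listed Polycomb target regulators only the segmentation gene gsb passed the test, at 0.73 ± 0.14 (adjusted p = 0.0418), and 0 did when adjusted over the list alone. None of the 4 measured Hox genes passed, the lowest adjusted p being 0.222 for Antp at -0.69 ± 0.22. The Hox genes lab, Ubx, abd-A and Abd-B were not among the genes measured, so nothing is known of them here. Of 15 haemocyte genes 1 fell, the phagocytosis receptor gene NimC1 at -1.52 ± 0.29, and the list median was 0.33. The 5 measured heat shock genes ranked higher as a set, with a median of 0.85 and adjusted p = 0.00309, but adjusted p = 0.623 with an estimated correlation. In that list 2 members rose and 0 fell, DnaJ-1 by 0.85 ± 0.14 and Hsp68 by 1.73 ± 0.30, and 3 rose when adjusted over the list alone, but 0 in the larval fit.

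Small shifts without a single called member gave set results in 4 further lists in mutant larvae. Male germline genes ranked lower over 37 genes (median -0.37, adjusted p = 0.00146), while higher ranks were found for mitochondrial ribosomal proteins over 69 genes (median 0.13, adjusted p = 0.00146), Notch targets over 13 (0.24, adjusted p = 0.026) and cell cycle genes over 20 (0.18, adjusted p = 0.0269). All 4 gave adjusted p = 0.976 with an estimated correlation and 0 members when adjusted over the list alone. Without the second larval control array the male germline list turned direction (adjusted p = 0.226), and the other three were lost, with adjusted p = 0.188 for mitochondrial ribosomal proteins, 0.586 for Notch targets and 0.426 for cell cycle genes. Without the first Jarid2 mutant array the mitochondrial ribosomal (0.199) and cell cycle (0.0944) calls were lost, and without the second the Notch call was (0.351).

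Counted over 18769 probe sets, 451 differed between Jarid2 mutant and control larvae, 251 higher and 200 lower, for 194 and 149 genes. In each of these 451 both arrays of one group lay above both of the other, which being called nearly ensures, so this lends the calls no support. Of all probe sets 35.9% showed that order, where chance gives 33.3%. A fit of the larval arrays alone called 154, 78 higher and 76 lower, and kept 20 of the 24 genes named by size, losing CG42716 (adjusted p = 0.191), Gr97a (0.101), Acbp3 (0.0663) and LysX (0.0607). The same 20 kept their calls with every array left out in turn. The larval fit also lost gsb (0.104), DnaJ-1 (0.14), Hsp68 (0.135) and Jon25Bi (0.0571). Without the first or the second Jarid2 mutant array the count was 166 or 212, and without either disc control array, which enters only the estimate of spread, it was 300.0.

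The arrays labelled E(z) RNAi were compared with the same larval controls, to ask what reduced E(z) changes. The E(z) probe set itself read higher in them. Every direction given here is therefore that of arrays in which no fall of E(z) was read. The pigmentation gene y rose by 4.17 ± 0.12 (adjusted p = 1.21e-05), reading 8.01 and 7.79 there and between 3.51 and 3.80 in the other 8 arrays. Whether genetic background, rather than what the label names, accounts for such changes was not tested. The phosphatase gene Alp7 rose by 4.15 ± 0.25, mthl8 by 4.08 ± 0.12, LysX by 3.90 ± 0.48 and the metallothionein gene MtnC by 3.49 ± 0.20. The peptidoglycan recognition protein gene PGRP-SB1 fell by 4.03 ± 0.16 (adjusted p = 6.37e-05). CG14852 changed by -5.13 ± 0.24, the immune-induced gene edin by -3.12 ± 0.44 and the chitinase gene Cht9 by -2.80 ± 0.40.

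Further rises were those of Oatp58Db (2.84), Prx6c (2.75), the piRNA pathway gene krimp (2.58), GstE1 (2.44), Acbp3 (2.40), CG18585 (3.53) and CG9903 (3.19). Further falls were those of Jhedup (-2.74), Cyp6a20 (-2.74), the Turandot stress gene TotB (-2.68), Tmlh (-2.67), Acp63F (-2.64), Acbp6 (-2.50), the cecropin gene CecB (-2.38) and CG11893 (-3.46).

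Some immune genes stood lower in the arrays labelled E(z) RNAi. Of 18 antimicrobial genes 3 fell, PGRP-SB1, CecB and Drsl3 (-1.51 ± 0.21), and 0 rose, against 3 and 1 when adjusted over the list alone and 2 and 0 in a fit of the larval arrays alone. The list ranked lower with a median of -0.25 and adjusted p = 0.0143, but adjusted p = 0.71 with an estimated correlation. The JAK/STAT list ranked lower over 12 genes with a median of -0.33, adjusted p = 0.00633, and adjusted p = 0.599 with an estimated correlation. Its one called member was TotB, also the one when adjusted over the list alone. Without the first larval control array the antimicrobial call was lost (adjusted p = 0.0811).

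Fat body genes also ranked lower in the arrays labelled E(z) RNAi, over 9 genes with a median of -0.37 (adjusted p = 0.0224, and adjusted p = 0.599 with an estimated correlation), and the lipase gene Lip3 fell by 1.71 ± 0.25, with 3 members lower adjusted over the list alone and 0 called in the larval fit. Muscle structural genes ranked higher over 20 genes with a median of 0.53 (adjusted p = 0.00107, and adjusted p = 0.976 with an estimated correlation), and the indirect flight muscle actin gene Act88F rose by 1.24 ± 0.14, the one member called either way. Cell cycle genes ranked higher over 20 genes with a median of 0.23 (adjusted p = 0.00309, and adjusted p = 0.976 with an estimated correlation), with 0 members called and 2 higher adjusted over the list alone. The male germline list ranked lower over 37 genes with a median of -0.51 (adjusted p = 0.00181, and adjusted p = 0.976 with an estimated correlation), although its one called member, the germline differentiation gene bam, rose by 0.98 ± 0.19. Without the first larval control array the fat body (adjusted p = 0.0776) and muscle (0.0811) calls were lost. Without the second larval control array the male germline list turned direction (adjusted p = 0.521) and the cell cycle call was lost (0.055). Without the second array labelled E(z) RNAi the fat body (0.0784), muscle (0.0822), cell cycle (0.0589) and male germline (0.789) calls were all lost.

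The measured Polycomb targets changed little in the arrays labelled E(z) RNAi. Of 78 regulators 2 rose, the POU factor gene pdm2 by 0.88 ± 0.12 and drm by 0.99 ± 0.21, and the homeobox gene bap fell by 0.66 ± 0.13, with the same counts adjusted over the list alone and 0 called in a fit of the larval arrays alone. None of the 4 measured Hox genes, which leave out lab, Ubx, abd-A and Abd-B, passed, the lowest adjusted p being 0.152 for pb at 0.34 ± 0.12. Of 64 detoxification genes 6 rose and 6 fell (15 and 11 adjusted over the list alone, 2 and 4 in a fit of the larval arrays alone), including GstE5 at 1.35 ± 0.14 and GstE9 at -2.26 ± 0.24. Of 40 midgut enzyme genes 5 rose and 1 fell (8 and 5 adjusted over the list alone, 2 and 0 in the larval fit), including Jon74E at 1.70 ± 0.18 and Mal-A6 at 1.04 ± 0.13.

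In all, 769 probe sets differed between the arrays labelled E(z) RNAi and control larvae, 493 higher and 276 lower, for 283 and 202 genes. The share that was higher depended on scaling, being 64.1% as deposited, 54.2% of 432 after quantile normalization of all arrays and 52.2% of 636 after quantile normalization within each tissue. Both arrays of one group lay above both of the other in all 769, which being called nearly ensures. Of all probe sets 46.6% showed that order, where chance gives 33.3%. A fit of the larval arrays alone called 169, 105 higher and 64 lower, of which 163 were among the 769, and a fit of these 2 groups alone called 2. Of the 24 genes named by size 21 kept their calls with every array left out in turn, and 2 in the fit of these 2 groups alone. The larval fit kept 21, losing Acbp3 (adjusted p = 0.109), CecB (0.0916) and Cht9 (0.0819), and it also lost Lip3 (0.0828), Drsl3 (0.0768), bam (0.0916), pdm2 (0.0798), drm (0.111), bap (0.145) and Mal-A6 (0.0664). The count was 273 without the second larval control array and 283 without the second array labelled E(z) RNAi, 379 without either disc control array and 393 without either disc mutant array.

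**Figure D2:**
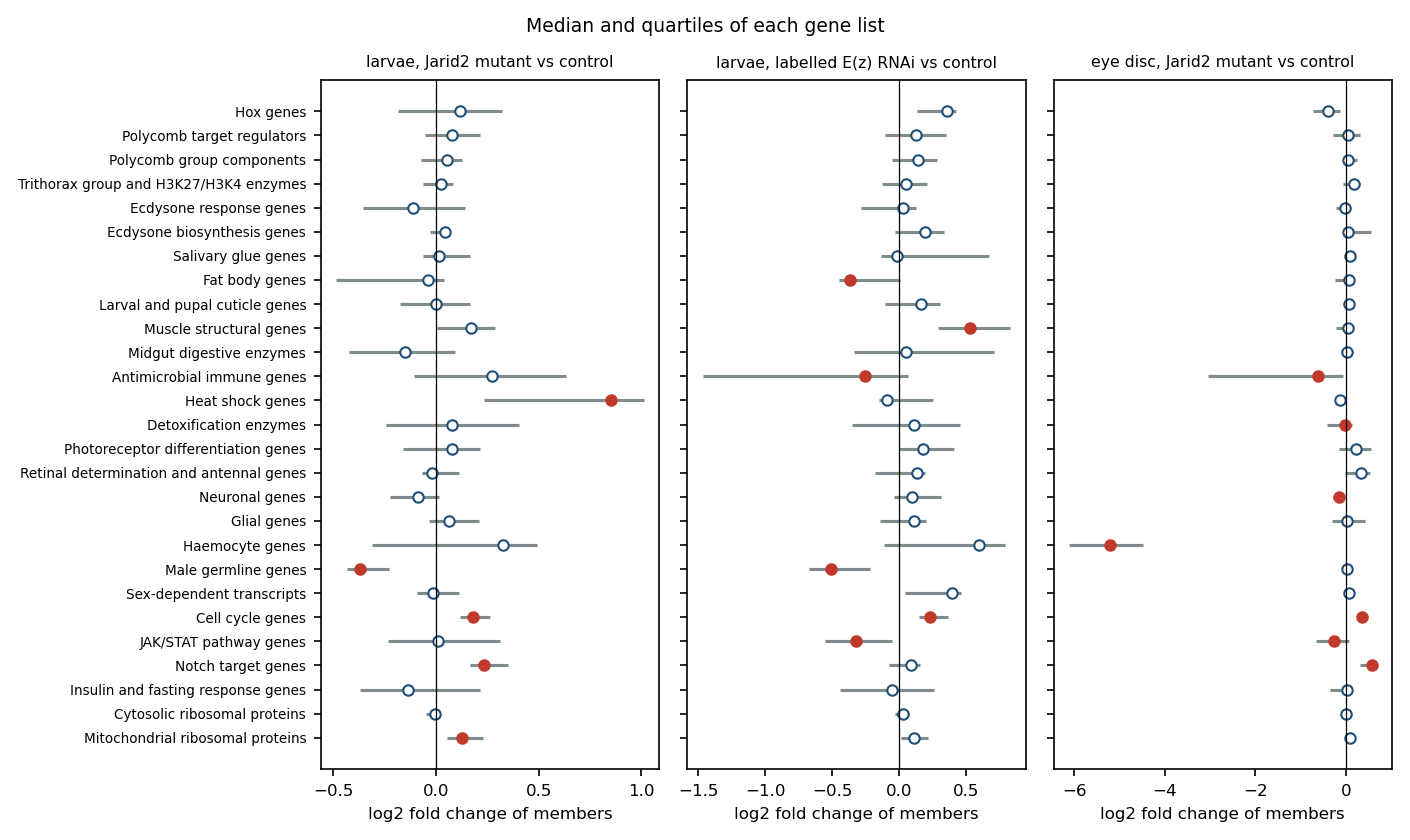
Median log2 fold change of the measured members of each of the 27 gene lists (points) with lower and upper quartiles (grey bars) in Jarid2 mutant larvae, in larvae labelled E(z) RNAi and in Jarid2 mutant eye discs, each against its control; red points have a camera adjusted p under 0.05 with the preset correlation and open points do not. The horizontal scales differ, and the haemocyte list in discs lies at -5.21 while its larval median with Jarid2 mutation is 0.33.

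Jarid2 mutant disc cells were compared with control disc cells to ask which transcripts depend on Jarid2 in that tissue. Genes of haemocytes, the blood cells of the fly, were far lower in the mutant arrays. The haemocyte surface gene He fell by 7.04 ± 0.46, from a mean of 12.49 to 5.44, the prophenoloxidase gene PPO1 by 6.64 ± 0.69, the GATA factor gene srp by 6.60 ± 0.26 and the phagocytic receptor gene eater by 5.80 ± 0.38. Of the 15 listed haemocyte genes 12 fell and 0 rose, and all 15 were lower when adjusted over the list alone. The list median was -5.21, with adjusted p = 2.21e-30 and adjusted p = 0.525 with an estimated correlation. It was also called by fry (adjusted p = 0.00415), which tests the list without comparing it with other genes. In a fit of the disc arrays alone 14 members were lower, and 12 were called in both fits.

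Other genes with the largest falls in mutant discs were mthl6 (-6.66), Nplp2 (-6.44), the basement membrane gene Glt (-6.31), the Nimrod-family gene NimB4 (-5.92), lectin-24Db (-5.78), NtR (-5.74), CG42807 (-6.75) and CG30148 (-6.31). Some antimicrobial genes fell with them. Of 18 measured 5 fell and 0 rose, against 7 and 0 adjusted over the list alone, including the immune regulator gene pirk at -3.44 ± 0.31, the drosomycin gene Drs at -4.61 ± 0.45, PGRP-LB at -3.12 ± 0.44 and the metchnikowin gene Mtk at -3.64 ± 0.55. That list had a median of -0.63 and adjusted p = 6.8e-06, with adjusted p = 0.525 with an estimated correlation. The JAK/STAT list ranked lower with a median of -0.26 (adjusted p = 0.00454, and adjusted p = 0.599 with an estimated correlation), where 2 of 12 fell, zfh1 by 3.38 ± 0.31 and et by 3.16 ± 0.40, and the same number fell when adjusted over the list alone. Detoxification genes ranked lower (adjusted p = 0.00309, and adjusted p = 0.976 with an estimated correlation) with 7 of 64 falling, although the list median was -0.02 and the mean -0.26. They included Cyp4e2 at -1.05 ± 0.12 and Ugt37D1 at -2.99 ± 0.36, and adjusted over the list alone 9 were lower and 1 higher.

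The disc groups also differed in ribosomal RNA signal and in other control probe sets of the array, none of which entered the tests, and those given here were picked after their values were seen. The middle 18S rRNA probe set had a mean of 10.60 with an SD of 0.08 in control discs and 8.47 with an SD of 0.81 in mutant discs, against 12.38 in control larvae. The control probe set AFFX-Dm-M62653-1_s_at read 12.99 in control discs, 10.03 in mutant discs and 2.89 in control larvae, and AFFX-Dm-AF292560-1_s_at read 13.07, 9.92 and 3.09. AFFX-Dm-K01486-1_at was higher in mutant than in control discs by 1.53. What these probe sets read is not given in the sources used here. Among bacterial spike-in controls AFFX-r2-Bs-lys-5_at was higher in mutant discs by 0.82, AFFX-r2-Bs-phe-5_at by 0.68 and AFFX-r2-Bs-thr-3_s_at by 0.64, while AFFX-r2-Bs-dap-5_at differed by -0.11. The excess of 3′ over 5′ signal in control and mutant discs was 0.59 (SD 0.05) and 0.74 (SD 0.18) for the actin control, 1.78 and 1.90 for eIF-4a, and 0.90 and 0.84 for GAPDH, which went the other way.

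**Figure D3:**
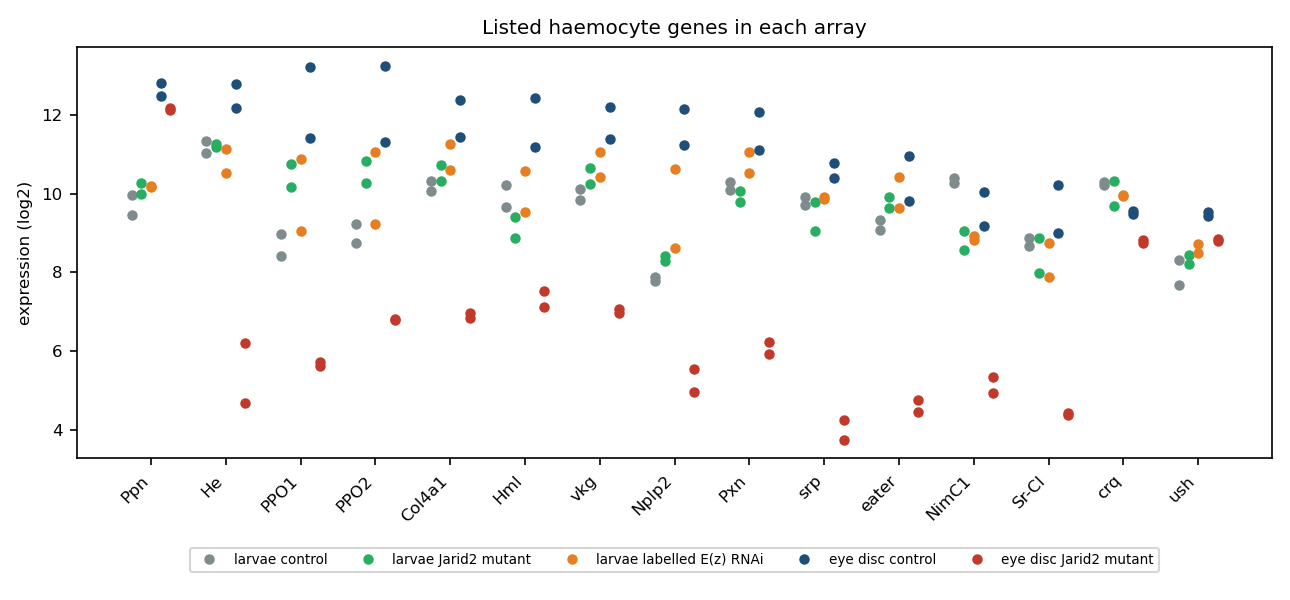
Expression on the log2 scale of the 15 listed haemocyte genes in each array, with the 5 groups in separate colours. For srp the control disc mean is 10.59 and the mutant disc mean 3.99, while the larval groups lie between 9.42 and 9.89.

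In mutant discs the ecdysone biosynthesis gene spok rose by 2.71 ± 0.21 (adjusted p = 0.000297), the Notch-responsive bHLH gene Hey by 2.08 ± 0.14, the neural bHLH gene tap by 1.73 ± 0.22, the forkhead gene fd59A by 1.87 ± 0.37 and the zinc finger genes erm and sna by 1.48 ± 0.29 and 1.34 ± 0.20. Of 13 Notch target genes 4 rose and 0 fell, against 7 and 0 adjusted over the list alone. These were Brd at 0.93 ± 0.15, Ocho at 0.90 ± 0.15, E(spl)m4-BFM at 0.71 ± 0.13 and E(spl)m5-HLH at 0.63 ± 0.11. The list median was 0.56, with adjusted p = 9.36e-05 and adjusted p = 0.976 with an estimated correlation. Haemocyte genes were far lower in the same mutant arrays, so a shift in the mix of sorted cells could raise other transcripts slightly. Whether this accounts for small rises in discs, here and in the lists below, was not tested. Of 11 ecdysone biosynthesis genes 3 rose, spok, nvd (0.84 ± 0.13) and sad (1.21 ± 0.20), the same number as adjusted over the list alone, though the set result did not pass (adjusted p = 0.209).

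Further rises in mutant discs were those of tut (1.57), GstE14 (1.43), flz (1.34), CG11294 (1.11), CG42272, at 1.19 with its brighter probe set and 0.35 with the other (adjusted p = 0.249), and Fatp2, at 1.44 with its brighter probe set and 0.18 with the other (adjusted p = 0.953). Of 25 photoreceptor genes 2 rose and 1 fell, the homeobox gene ro (0.93 ± 0.14), the proneural gene ato (0.86 ± 0.15) and sty (-0.72 ± 0.14), against 9 and 2 adjusted over the list alone, and the set result did not pass (adjusted p = 0.261). Of 17 retinal and antennal genes so (0.83 ± 0.10) and dan (0.72 ± 0.13) rose and oc (-1.28 ± 0.19) fell, against 8 and 1 adjusted over the list alone, and the set result did not pass either (adjusted p = 0.0796). Of 78 Polycomb target regulators 5 rose and 3 fell, against 9 and 3 adjusted over the list alone, including tll at 1.13 ± 0.16 besides sna, so and zfh1. Over all 11982 genes 79 rose and 334 fell. Rises, though few, were thus more frequent in this list than among all genes, while falls were about as frequent. That difference was not tested. The median of that list was 0.04, its mean was -0.03, and its set test, which asks for a shift in one direction, did not pass (adjusted p = 0.693). None of the 4 measured Hox genes, which leave out lab, Ubx, abd-A and Abd-B, was called, the lowest adjusted p being 0.0773 for Antp at -0.95 ± 0.22.

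Markers of other cell types in the disc preparations were mixed. Of 13 glial genes wrapper (-1.41 ± 0.16), repo (-1.68 ± 0.23) and Gs2 (-1.05 ± 0.16) fell and gcm (1.15 ± 0.18) rose, against 3 and 2 adjusted over the list alone. Of 9 fat body genes 0 were called, with a median of 0.06, and of 20 muscle genes 0 were called. Of 40 midgut enzyme genes 3 fell, the galactosidase gene Gal (-4.99 ± 0.17), the mannosidase gene LManI (-5.39 ± 0.36) and Mal-A5 (-1.13 ± 0.18). Neuronal genes ranked slightly lower over 21 genes (median -0.16, adjusted p = 0.00691, and adjusted p = 0.976 with an estimated correlation) with 0 called and 1 lower adjusted over the list alone. That call was lost without the second control disc array (adjusted p = 0.439) or the second mutant disc array (0.425). Cell cycle genes ranked higher over 20 genes (median 0.35, adjusted p = 9.36e-05, and adjusted p = 0.976 with an estimated correlation) with 0 called and 5 higher adjusted over the list alone.

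In discs 490 probe sets differed between Jarid2 mutants and controls, 97 higher and 393 lower, for 79 and 334 genes. In all 490 both arrays of one group lay above both of the other, which being called nearly ensures, and 52.6% of all probe sets showed that order. A fit of the disc arrays alone called 428, of which 328 were lower and 344 were among the 490. Of the 24 disc genes named by size, 15 kept their calls with every array left out in turn and 18 with the replicate block. The others lost them without at least 1 array, with adjusted p reaching 0.284 for tut, 0.261 for erm, 0.240 for fd59A, 0.180 for CG11294, 0.0867 for flz, 0.0847 for sna, 0.0632 for CG42272, 0.0570 for Fatp2 and 0.0510 for GstE14. The fit of the disc arrays alone kept 21, losing fd59A (adjusted p = 0.113), erm (0.113) and CG11294 (0.0823), and it also lost PGRP-LB (0.059), E(spl)m4-BFM (0.0532), E(spl)m5-HLH (0.0771), ato (0.0626), dan (0.0583), sty (0.0529), oc (0.0538) and Mal-A5 (0.0735). In that fit 2 Notch targets rose, 3 antimicrobial and 5 detoxification genes fell, 3 photoreceptor genes and 1 retinal gene rose, and 4 Polycomb target regulators rose and 2 fell. The count was 276 without the second control disc array, 290.0 without the first mutant disc array and 244 without the second.

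The Jarid2 effect in discs was set against that in larvae by an interaction term, which passed for 542 probe sets, 148 with a more positive and 394 with a more negative effect in discs. Among the negative ones were genes that fell in mutant discs and not in mutant larvae: PPO1 (-8.41 ± 0.97), CG42807 (-7.49 ± 0.80), CG30148 (-7.18 ± 0.56), mthl6 (-7.14 ± 0.67) and He (-7.09 ± 0.65). Among the positive ones were Antdh (5.29 ± 0.43), CG11893 (5.16 ± 0.41), CG17191 (5.33 ± 0.30), CG32198 (5.35 ± 0.71) and Elovl7 (7.48 ± 0.25), which were lower in mutant larvae. In control and mutant discs Elovl7 had means of 3.63 and 3.66, CG17191 of 2.96 and 3.31, CG11893 of 2.96 and 3.05, Antdh of 4.31 and 4.23 and CG32198 of 5.54 and 5.48, so these differences came mostly from the larval arrays. A fall in discs could not have been read for Elovl7, CG17191 and CG11893, which lay below the lower quartile of the disc arrays (4.20 to 4.27). Antdh lay close to that quartile and CG32198 just below the disc medians (5.55 to 5.62). A fall as large as in larvae could not have been read for these genes either. The count was 293 without the first Jarid2 larval array and 328 without the second, 327 without the second control disc array, and 327 or 297 without the first or second mutant disc array.

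As sets, haemocyte genes differed more negatively in discs than in larvae by a median of -5.25 (adjusted p = 5.93e-23, and adjusted p = 0.525 with an estimated correlation), with 12 of 15 called and 14 adjusted over the list alone. A response of these genes cannot be told apart from fewer blood cells in the mutant disc samples. Whether fewer blood cells also lowered the antimicrobial genes was not tested. The other sets with a more negative difference in discs were antimicrobial genes (median -1.52, adjusted p = 0.000423, and adjusted p = 0.599 with an estimated correlation), heat shock genes (-0.98, adjusted p = 0.00228, and adjusted p = 0.623 with an estimated correlation) and detoxification genes (-0.24, adjusted p = 0.00744, and adjusted p = 0.976 with an estimated correlation). Of these, 5 antimicrobial genes were more negative and 1 more positive (7 and 1 adjusted over the list alone), 1 heat shock gene was more negative (3 adjusted over the list alone), and 7 detoxification genes were more negative and 4 more positive (12 and 8 adjusted over the list alone). The detoxification call was lost without the first larval control array (adjusted p = 0.0811) and after quantile normalization of all arrays (0.0652). Among single genes the difference passed for spok (2.74 ± 0.29), sad (2.34 ± 0.28) and Brd (1.19 ± 0.21), all more positive in discs, and for DnaJ-1 (-0.98 ± 0.20).

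Calls shared by the Jarid2 comparisons in larvae and discs were few. There were 6 probe sets higher in both, where independent lists of these sizes would share 1.30, 11 lower in both (4.19), and 23 with opposite directions (6.29), and the fold changes were uncorrelated across probe sets (r = -0.00775, Spearman rho = 0.0658). Besides Jarid2, genes lower in both included GILT3, NimC1, repo and GstD3, and mthl8 was higher in both, by 4.89 in larvae and 1.28 in discs. The gene sad fell by 1.13 in larvae and rose by 1.21 in discs, and HP1D3csd rose by 2.48 in larvae and changed by -4.12 in discs. These genes were picked from the shared list after their values were seen. In the fit of the larval arrays alone repo (adjusted p = 0.14), GstD3 (0.0846) and sad (0.149) lost their larval calls. The 17 shared calls became 7 in fits of each tissue alone, and without 1 array they numbered 7 or 10.0 without the first or second Jarid2 larval array, 11 or 9 without the first or second control disc array, and 6 or 7 without the first or second mutant disc array.

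Larval changes in Jarid2 mutants and in the arrays labelled E(z) RNAi were set side by side to ask how far they coincided, with the caveat that E(z) read higher in the latter. Both sets of larvae had higher mthl8, LysX, Prx6c, GstE1 (2.49 in Jarid2 mutants), CG9903 (2.99 and 3.19) and Acbp3, and both had lower CG11893, Tmlh and CG14852 (-4.57 and -5.13). In numbers, 82 probe sets were higher in both and 62 lower in both, for 70 and 47 genes, where independent lists of these sizes would share 6.59 and 2.94, and 20 went in opposite directions (8.94). The 144 made up 31.9% of the Jarid2 calls and 18.7% of the calls in the arrays labelled E(z) RNAi, and 35 of them also differed between the Jarid2 mutant and those arrays.

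Both comparisons used the same 2 control arrays, whose error enters both sets of fold changes, so part of the excess may come from the shared controls. With unchanged groups simulated against shared controls at the pooled larval spread, shared calls averaged 0.84 with a highest of 6 in 100 simulations. Such groups gave a mean of only 5.26 Jarid2 calls, against 451 in the data. Their shared counts therefore cannot be set against the 144. The pooled spread was too small for the control arrays, whose difference had an SD of 0.496 across probe sets. The simulation was therefore repeated with the spread of each group, a choice made after the data were seen. Shared calls then averaged 2.78 with a highest of 14, again among unchanged groups. Across probe sets the 2 sets of fold changes correlated at r = 0.454 (Spearman rho = 0.410), below the simulated mean r of 0.498 at the pooled spread and 0.670 at the spread of each group. Changes in 1 comparison alone lower r, while changes common to both can raise it. The low r therefore cannot be read on its own, and the covariance was compared as well. It was 0.0759, against a simulated mean of 0.0277 at the pooled spread and 0.0612 (0.0538 to 0.0688) at the spread of each group, a difference of 0.0148 from the latter. With 1 control array for each comparison, also chosen after the data were seen, the covariance was -0.00435 (r = -0.0181) one way round and 0.0330 (r = 0.160) the other. Calls made that way were shared in the same direction by 93 and 76 probe sets and in opposite directions by 19 and 7, where independent lists would share 5.73 and 3.26 in the same direction. The fit of the larval arrays alone gave 51 shared calls. Without the first larval control array r was 0.677. The shared count was 69 or 75 without the first or second Jarid2 mutant array and 92 without either disc control array.

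**Figure D4:**
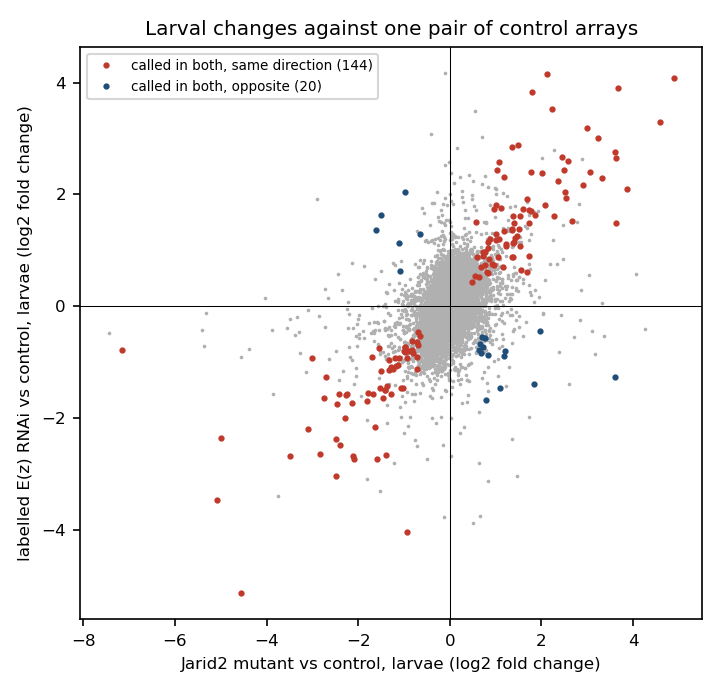
Log2 fold change against the same 2 control arrays of each probe set in Jarid2 mutant larvae (horizontal) and in larvae labelled E(z) RNAi (vertical). Red points are the 144 probe sets called in the same direction in both comparisons, blue points the 20 called in opposite directions, and grey points all others.

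The direct contrast of Jarid2 mutant larvae with the arrays labelled E(z) RNAi did not use the shared controls. Some immune genes were higher in the Jarid2 mutants, with edin at 3.95 ± 0.44, CecB at 3.73 ± 0.50, PGRP-SB1 at 3.09 ± 0.16 and Drsl3 at 1.43 ± 0.21. CG14219 (4.50 ± 0.49), Cyp4p2 (3.54 ± 0.20) and CG42716 (3.50 ± 0.80) were also higher. Elovl7 (-6.97 ± 0.18), Jarid2 (-5.21 ± 0.24), CG32198 (-4.99 ± 0.50), Antdh (-4.65 ± 0.30) and y (-4.27 ± 0.12) were lower in the Jarid2 mutants. E(z) was lower there as well, by -0.96 ± 0.15 (adjusted p = 0.011), against the direction that the labels give.

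Of 18 antimicrobial genes 3 were higher in the Jarid2 mutants and 0 lower (4 and 0 adjusted over the list alone), with a set median of 1.11 (adjusted p = 0.00146, and adjusted p = 0.599 with an estimated correlation). Of 5 heat shock genes 3 were higher, DnaJ-1 (1.00 ± 0.14), Hsp26 (1.33 ± 0.24) and Hsp68 (1.35 ± 0.30), with a set median of 1.00 (adjusted p = 0.00574, and adjusted p = 0.623 with an estimated correlation) and the same count adjusted over the list alone. The JAK/STAT list was higher (median 0.31, adjusted p = 0.0201, and adjusted p = 0.623 with an estimated correlation) with upd2 (0.92 ± 0.15), dome (0.84 ± 0.15) and vir-1 (1.53 ± 0.30) called among 12, and 4 adjusted over the list alone. Muscle genes were lower (median -0.36, adjusted p = 0.0428, and adjusted p = 0.976 with an estimated correlation) with Act88F alone called among 20, at -1.07 ± 0.14, and also alone when adjusted over the list alone. The JAK/STAT call was lost without the second Jarid2 mutant array (adjusted p = 0.053) and the muscle call without that array (0.132), without the second array labelled E(z) RNAi (0.789) or after quantile normalization (0.0676).

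In the direct contrast 1146 probe sets passed, of which 696 were lower in the Jarid2 mutants. The share that was higher was 39.3% as deposited, 51.8% of 645 after quantile normalization of all arrays and 51.2% of 918 within each tissue. Of the 10 genes named by size 8 kept their calls with every array left out in turn, CG42716 and CecB losing theirs. The larval arrays alone gave 252 calls, 247 of them among the 1146, in which CG42716 (adjusted p = 0.152), Drsl3 (0.0678), DnaJ-1 (0.0658), Hsp26 (0.101), Hsp68 (0.138), upd2 (0.0837), dome (0.0965), vir-1 (0.117) and E(z) (0.064) no longer passed, so that 0 heat shock and 0 JAK/STAT genes were called. The count was 294 or 442 without the first or second Jarid2 mutant array, 433 without the second array labelled E(z) RNAi, 650.0 without either disc control array and 705 without either disc mutant array.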

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

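Of the tests weighed for the haemocyte genes, every one was chosen only after the result was seen. In Jarid2 mutant discs the listed haemocyte genes had a median of -5.21, and the Jarid2 effect on them in discs differed from that in larvae by -5.25. Fat body attached to the control discs did not account for it, since fat body genes had a median of 0.0607. Whole mutant larvae showed no fall of these genes as a set, with a median of 0.33 and a lower quartile of -0.31. Of 15 members 1 fell, NimC1. This argues against a loss of blood cells, or a fall of these genes within them, in those larvae. The discs came from other samples, so neither is excluded there. Blood cells that were in the control sort and were depleted from the mutant sort may account for the -5.21, but this cannot be told apart from fewer blood cells attached to mutant discs, because sort and genotype coincide and the fraction kept is not given in the sources used here.

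Of the tests weighed for E(z), both were chosen only after the result was seen. E(z) was higher in the arrays labelled E(z) RNAi by 0.99 ± 0.15. An exchange of labels with the larval controls did not account for it, because E(z) in Jarid2 mutant larvae differed from the controls by 0.0264 ± 0.15, so the controls lay at the level of a group not labelled as altered in E(z). A probe set that reads the transgene as well as the gene may give a rise of 0.99, which cannot be told apart from a real rise because the probe and hairpin sequences were not used here.

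Of the tests weighed for the changes common to both larval comparisons, some settings were chosen only after the result was seen. These were the spread of each group, the separate control arrays and a margin on the stage test. Sampling error of the shared controls did not account for all of the shared calls. With 1 control array for each comparison, same-direction calls outnumbered opposite ones 4.89 and 10.9 times, the 2 ways round. A part of the shared calls may still come from that error, and its size was not settled. Of the covariance of 0.0759 over all probe sets, the difference between the 2 control arrays contributed 0.0616. For the rest, a mean of 0.0143 with separate controls, sampling error cannot be told apart from a common response. The planned bound of 0.0327 understated the control spread, and the highest value at the spread of each group was 0.0688. Separate controls gave -0.00435 and 0.0330, with only 2 control arrays. A difference of developmental stage in the control arrays could contribute, and the mean larval change correlated with the difference between the control replicates at r = 0.295 across probe sets, which are not independent replicates. That value lay just inside the bound that was set in advance for stage not being the cause. With a margin around that bound, added after the value was seen, stage and other causes cannot be told apart.

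For the other results no further test of a cause was chosen, before or after the result was seen, apart from that of linked background given below. The Jarid2 effect differed between discs and larvae for 542 probe sets. Positive differences were Antdh at 5.29, CG11893 at 5.16, CG17191 at 5.33, CG32198 at 5.35 and Elovl7 at 7.48, which were lower in mutant larvae. In discs CG11893, CG17191 and Elovl7 lay below the lower quartile in both groups, where a fall could not be read. A fall as large as in larvae could not be read in discs for Antdh and CG32198 either. Negative differences were CG42807 at -7.49, CG30148 at -7.18 and mthl6 at -7.14, with PPO1 at -8.41 and He at -7.09, which belong to the haemocyte genes weighed above. Jarid2 itself differed by 2.43. As lists, antimicrobial genes differed by a median of -1.52, heat shock genes by -0.98 and detoxification genes by -0.24. The control probe set AFFX-Dm-K01486-1_at was higher than in control larvae by 4.43 in Jarid2 mutant larvae and by 7.85 in the arrays labelled E(z) RNAi. The control probe set AFFX-Dm-U43284-1_s_at was higher by 4.72 in Jarid2 mutant larvae.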

How the results depend on the processing

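Precision was limited by 2 arrays per group, by a larval spread of 0.160 against 0.0978 in discs, and, as the limit of depth for arrays, by signal over background for dim probe sets. The planned log2(value + 16) scale was not run because the values were already log2, and the interaction was not fitted from one tissue or from the compared groups alone, where it is not possible. Where a value moved, the cause was not tested.

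Scaling and filters moved the counts for labelled E(z) RNAi and for the direct contrast, which were 769 and 1146. They were 432 and 645 after quantile normalization of all arrays, 493 and 746 after median centring, and 409 and 628 without the dimmest 30% of probe sets. Calls shared by larvae and discs, 17 as fitted, were 8 after quantile normalization. Without the dimmest probe sets the JAK/STAT call was lost for labelled E(z) RNAi (adjusted p = 0.271) and for the direct contrast (0.149). Single calls were also lost for neuronal genes in discs after quantile normalization (adjusted p = 0.0633), for muscle genes in the direct contrast after quantile normalization within tissues (0.0515), for cell cycle genes in mutant larvae after median centring (0.0516) or with the mean of all probe sets (0.0539), and for JAK/STAT genes in the direct contrast with larval arrays alone (0.0572).

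Arrays of one tissue alone gave 154 calls for larval Jarid2, 169 for labelled E(z) RNAi and 252 for the direct contrast, with 51 shared larval calls and 7 shared between larvae and discs. The compared groups alone gave 112, 2 and 185, with 1 and 6 shared. Array weights gave 288, 199, 1332 for discs and 757 for the direct contrast, with 76 shared larval calls. A 2-fold minimum gave 286, 293 and 399, with 95 shared. E(z) stayed at 0.99 but lost its call in all of these fits. Of the 26 list calls 0 were left with an estimated correlation and 7 list calls were made by fry.

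Treating the replicate number as a block gave 192 calls for larval Jarid2, 188 for labelled E(z) RNAi, 306 for discs, 315 for the interaction and 355 for the direct contrast, with 65 shared larval calls, 8 shared between larvae and discs, and E(z) at 0.99 without its call. The replicate numbers did not pair the arrays, since the difference between replicates correlated between groups at r from -0.422 to 0.0870 across probe sets. A crossed pairing, chosen after the data were seen, gave 393, 670.0, 472, 505 and 857 calls.

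Leaving out each array in turn assumes that the lone sample left in a group varies like the other groups. Calls ranged from 166 to 446 for larval Jarid2, 273 to 641 for labelled E(z) RNAi, 244 to 519 for discs, 293 to 533 for the interaction and 294 to 1280.0 for the direct contrast. Shared larval calls ranged from 69 to 161, those of larvae and discs from 6 to 14, the larval correlation from 0.373 to 0.677 and list calls from 23 to 32. E(z) ranged from 0.83 to 1.14, and Jarid2 from -5.41 to -5.25 in larvae and -3.32 to -2.48 in discs. The male germline list reversed without the second larval control array, for larval Jarid2 (adjusted p = 0.226) and for labelled E(z) RNAi (0.521). Over all arrays left out, its adjusted p ranged from 1.08e-11 to 0.226 for larval Jarid2 and from 1.97e-10 to 0.789 for labelled E(z) RNAi, the lowest without the first larval control array and the 0.789 without the second array labelled E(z) RNAi.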

Other observations

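A few members of the nutrient-response and salivary glue lists changed in the larval arrays without a set result, with adjusted p = 0.609 and 0.471 in Jarid2 mutants and 0.324 and 0.653 in the arrays labelled E(z) RNAi. In the arrays labelled E(z) RNAi, where E(z) itself read higher, 1 of 18 insulin and fasting response genes rose, the transcription factor gene sug by 1.34 ± 0.18, and 2 fell, the glucosidase gene tobi by 1.39 ± 0.18 and the fatty acid synthase gene FASN1 by 1.09 ± 0.19, against 1 and 3 adjusted over the list alone. In Jarid2 mutant larvae the lipase gene bmm rose by 0.77 ± 0.11, the only member called. Of 12 salivary glue genes 1 rose in Jarid2 mutant larvae, Sgs5bis by 1.55 ± 0.12, and 2 in the arrays labelled E(z) RNAi, Sgs5bis by 0.64 and ng2 by 1.83. In a fit of the larval arrays alone bmm (adjusted p = 0.0979) did not pass in Jarid2 mutants, and tobi (0.0719), FASN1 (0.111), Sgs5bis (0.111) and ng2 (0.153) did not pass in the arrays labelled E(z) RNAi.

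Single members of other lists changed in mutant larvae: TotB fell by 2.11 ± 0.18, repo by 1.23 ± 0.23, sad by 1.13 ± 0.20 and PGRP-SB1 by 0.94 ± 0.16. Of 29 ecdysone response genes 0 passed there, 1 fell in the arrays labelled E(z) RNAi (Eig71Ee at -0.71) and 1 in mutant discs (Cth at -0.59). Of 43 cuticle genes 0 passed in mutant larvae, 2 fell in the arrays labelled E(z) RNAi (TwdlL at -0.80 and Lcp65Af at -1.34) and 1 fell in mutant discs (Cpr49Ac at -2.32). None of 14 trithorax group genes, 41 cytosolic ribosomal protein genes or 7 sex-dependent transcripts passed in any of these 3 comparisons. Of 18 Polycomb group genes Jarid2 alone passed in Jarid2 mutants of either tissue, and E(z) alone in the arrays labelled E(z) RNAi. In fits of one tissue alone repo (adjusted p = 0.14), sad (0.149), PGRP-SB1 (0.13), Eig71Ee (0.109), TwdlL (0.158), Cth (0.0583) and E(z) (0.078) did not pass.

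The pigmentation gene e read 13.63 and 7.47 in the larval controls, 10.93 and 13.17 in the Jarid2 mutants and 13.44 and 9.96 in the arrays labelled E(z) RNAi, so replicates of one group were far apart for this gene. The eye colour gene ry, picked after its values were seen, read 8.72 and 8.65 in the larval controls and 6.42 and 6.24 in the Jarid2 mutants, a fall of -2.36 ± 0.19 (adjusted p = 0.000703, and 0.0115 with the larval arrays alone), and 8.72 and 9.24 in the arrays labelled E(z) RNAi.

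For linked genetic background neither of the tests was chosen only after the result was seen. The hypothesis is that variants near the Jarid2 insertion, rather than loss of Jarid2, could account for some changes. Variants elsewhere in the genome are not covered by these tests, and the background of the arrays labelled E(z) RNAi was not tested. Among the 100 measured genes nearest to Jarid2, 3 were called in larvae against 337 of 11792 others (odds ratio 1.05, Fisher exact p = 0.764), and 6 in discs against 405 (odds ratio 1.79, p = 0.161), so background and Jarid2 loss cannot be told apart for these genes. A test would be expression in the mutant with a Jarid2 transgene, with the changes of mthl8 and Elovl7 expected to revert if Jarid2 causes them.

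For the haemocyte genes the tests were chosen only after the result was seen. A hypothesis is that fewer blood cells were sorted with the mutant disc cells, which could give the median of -5.21. It predicts that counts of blood cells on mutant and control discs before sorting are alike, while a loss of attached blood cells predicts fewer on mutant discs. The larval median of 0.33 showed no fall of haemocyte genes as a set in whole mutant larvae. Those larvae were other samples than the discs, so this does not exclude fewer blood cells in the disc donors.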
